A study of Mus musculus with 2 samples.

How the data were processed

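Chromatin loops bound by the bromodomain protein BRD2 were measured by ChIA-PET in the mouse embryonic stem cell line V6.5. In ChIA-PET, chromatin is precipitated with an antibody, here against BRD2, nearby DNA ends are ligated to each other, and paired-end sequencing reads out which places of the genome were joined. The series has 2 samples, labelled as replicates 1 and 2 of the same untreated wild-type cells, and therefore 1 group. Per the labels' protocols, the cells were grown on irradiated mouse fibroblasts in medium with serum and LIF, the nuclei were sonicated, and the libraries were made by tagmentation after proximity ligation and sequenced on an Illumina HiSeq 2000.

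The deposited data used here are a single list of loops. Per the file header, the list holds high-confidence interactions of the merged dataset, so the authors pooled the replicates before or while making it. Values per replicate were not used here, and the spread between replicates is unknown. The submitters' processing notes name cutadapt, Bowtie and the genome build mm9. The interaction caller, its thresholds, the filter on ligation products and the number of reads are not given in the sources used here. The sequencing depth behind each loop is therefore unknown, and no loop that is missing from the list can be called absent.

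Each loop has a position and 1 score. The scores are the authors' own values as deposited. They are whole multiples of 1000 in all 7732 loops, with a lowest and commonest value of 2000. A score of 1000 per paired-end tag would give these values, but no header states the unit, so the values are reported as scores. The start and end columns of the first anchor were read as the left and right outer edges of a loop. This reading is an inference, and all lengths, anchors, partners and groups below rest on it. The columns for a second anchor repeat the left edge in all 7732 loops and were not used. A right edge that lay less than 5000 bp after a left edge was taken as the other side of the same anchor. This rule left no doubtful cases, because 2 edges of the same kind were never closer than 5140 bp, and a left edge never followed a right edge by less than 5006 bp. Anchors found in this way were 100 to 1663 bp wide. Positions are given as the file lists them, on mm9 (not converted). Loop length is the distance between the outer edges. It replaced the distance between anchor midpoints planned before the data were examined, since both edges of both anchors were known for only 1309 loops.

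Genes could not be placed at the anchors. The gene table used here is on GRCm38.p6, another build: on 5 chromosomes a loop edge lies beyond the last gene of that table, for example at position 152408294 of chromosome 7. Promoter anchors, loops between promoters, scores by promoter class and the gene lists fixed before the data were examined were therefore not analysed here. The table served only for the number of protein-coding genes on each of the 20 chromosomes that hold loops (21631 genes in all), which was the expectation for loops per chromosome planned for the case that chromosome lengths of mm9 were not used.

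Medians have 95% percentile bootstrap intervals from 2000 resamples, over loops and over whole connected groups of anchors. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Score and length were related by Spearman's rho and by Pearson's r of log10 values across loops, with 100000 permutations (two-sided, 10000 for alternatives and single chromosomes). Loops of a chromosome were set against expectation with a two-sided exact binomial test, Benjamini-Hochberg adjusted over 20 chromosomes, at a threshold of 0.05. Loops share anchors and are not independent replicates, so these p-values describe the list and not the variation between cultures. For the ratios per chromosome, an interval from resampling whole connected groups is given as well. Anchors joined directly or through other anchors form a connected group. All steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

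The steps were tested on simulated data. Of 1613 simulated anchors, 100% were found again with their number of partners. They were narrower than the limit for pairing edges and spaced wider than it, so this shows only that the rule ran as written. Of 100 unrelated lists of 7732 loops, 4 gave a permutation p under 0.05 for score against length, and a planted negative relation was recovered. A chromosome planted far below its expectation was found in 100 of 100 lists, and 2 of 100 lists without an effect had any chromosome past the threshold. Weaker departures were not planted. In those simulated lists the loops were independent, unlike real loops.

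The loops and anchors named in the text follow a rule written before the data were examined: the 10 loops with the highest score (3 loops tie at the tenth score of 22000 and the first by position is named), the 10 anchors with the most partners (7 tie at 9 partners, ordered by summed score) and the 5 longest loops. Connected groups and one-sided anchors were singled out after their values were seen. The alternatives were a minimum score of 3000, leaving out chromosome X, short loops, the top 1% of scores or loops over 5 Mb, 1 loop per connected group, other rules for joining edges, and other expectations per chromosome.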

Results

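BRD2 is a member of the BET family, whose bromodomains bind acetylated histones at active promoters and enhancers. The study, as its title and design text state, concerns the part BRD2 plays in transcription initiation by RNA polymerase II. Here, the places of the genome that BRD2-bound chromatin brings together were listed in untreated V6.5 cells, a mouse embryonic stem cell line. The 2 replicates entered a single merged list, so the design gives no comparison between conditions, and each value below has no replicate error. The list held 7732 loops with a summed score of 23813000. Each was read as a left and a right edge on the same chromosome, so contacts between chromosomes lie outside what the list can show. Its sequencing depth is unknown.

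Most BRD2 loops were short. The median length was 28.6 kb, with a bootstrap interval of 27.7 to 29.6 kb over loops and 27.6 to 29.6 kb over connected groups. The lower quartile was 12.6 kb and the upper quartile 75.9 kb. Loops of up to 100 kb numbered 6279, or 81.2% of the list. Only 53 loops lay between 500 kb and 1 Mb and 39 between 1 and 5 Mb, whereas 162 loops, or 2.10%, were longer than 5 Mb. No loop was shorter than 5256 bp, so contacts below about 5 kb lie outside what the list can show.

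Scores were low for most listed loops and, among these, fell with length. The thresholds of the caller are not given, so whether they depended on length and shaped this relation is unknown. The lowest score, 2000, was held by 4472 loops, or 57.8% (exact 95% interval 56.7 to 58.9%). A score of 10000 or more was held by 153 loops and one of 20000 or more by 19. Among loops of 5 to 10 kb, 57.7% had a score of 3000 or more (interval 55.0 to 60.4%), with a mean score of 3621 ± 2527 (SD over 1351 loops). In loops of 20 to 50 kb this share was 41.8% (39.7 to 44.0%), and in loops of 100 to 500 kb it was 27.4% (24.9 to 30.1%). The share was 7.55% over the 53 loops of 500 kb to 1 Mb and 15.4% over the 39 loops of 1 to 5 Mb (5.86 to 30.5%). Above 5 Mb it was 4.32% (1.75 to 8.70%), with a mean score of 2068 ± 355 (SD over 162 loops). Across the 7732 loops, Spearman's rho between score and length was -0.27 and Pearson's r of the log10 values was -0.24, each with a two-sided permutation p of 1e-05, the smallest that the permutations can give.

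**Figure D1:**
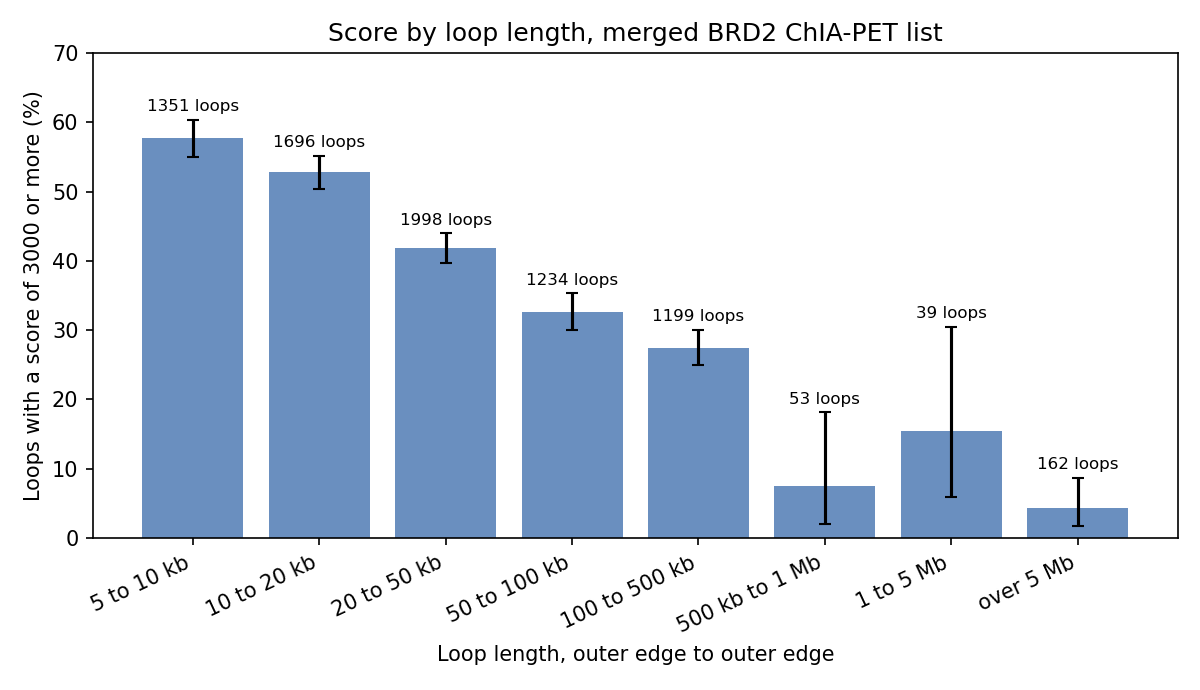
Share of loops with a score of 3000 or more (vertical axis, %) in 8 classes of loop length (horizontal axis); bars are shares over the loops of a class, whose number stands above, and error bars are exact 95% intervals covering counting error only. The share falls from 57.7% at 5 to 10 kb to 27.4% at 100 to 500 kb and 4.32% above 5 Mb.

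The strongest contact joined 77169056 to 77187248 on chromosome 15, a loop of 18.2 kb with a score of 52000. Second was the loop from 88383662 to 88400259 on chromosome 1, 16.6 kb long, with a score of 42000. Its right anchor was also the left anchor of a loop to 88422587 with a score of 26000, so that 2 of the 10 strongest loops formed a chain. A score of 30000 was reached by the loop from 32018323 to 32030144 on chromosome 2 and by the loop from 133312455 to 133377250 on chromosome 4. The latter, at 64.8 kb, was the longest of the 10. On chromosome 5 the loop from 118885698 to 118896164 had a score of 27000, and on chromosome 15 the loop from 81344621 to 81354024 had one of 25000. The remaining 3 were the loop from 40947289 to 40970170 on chromosome 19 (score 24000), the one from 37107539 to 37139725 on chromosome 17 (score 23000) and the one from 118745546 to 118781501 on chromosome 4 (score 22000). Each anchor of these 10 loops had at least 2 partners. The genes at these places were not analysed here.

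BRD2 anchors were often shared between loops. The loop edges resolved into 9407 anchors, of which 3547, or 37.7% (36.7 to 38.7%), had 2 or more partners and 642, or 6.82%, had 4 or more. The mean was 1.64 ± 1.08 partners (SD over anchors). Both edges were seen for the 2084 anchors that had partners on each side, and their median width was 350 bp (quartiles 212 and 604 bp). Of the 7531 loops of up to 1 Mb, 4524, or 60.1%, joined neighbouring anchors, and 3007 passed over 1 or more anchors. Only the anchors of these 7531 loops were counted here, not those seen only in longer loops. Of 7933 sets of 3 anchors joined by at least 2 such loops, 990, or 12.5%, were closed by the remaining loop.

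Several of the 10 anchors with the most partners shared a cluster. The first, at 88383662 to 88384782 on chromosome 1, had 11 partners, 5 upstream and 6 downstream, and a summed score of 90000. Of its loops, 2 were longer than 5 Mb, and without these it had 9 partners. The anchor at 88368524 to 88369778 had 10 partners, none of them over 5 Mb away, and the anchor at 88399839 to 88400259 had 9 and the largest summed score of the 10 named anchors, 120000. With loops over 5 Mb set aside, these 3 belonged to a single group of 18 anchors and 36 loops with 28 closed triangles. On chromosome 17, the anchor at 71183761 to 71183880 had 10 partners within a group of 16 anchors that spanned 295 kb. Also on chromosome 17, the anchor at 37139336 to 37139725 had 9 partners. Its group of 11 anchors spanned 277 kb and held 31 loops with 39 closed triangles. The anchor at 31945047 to 31945477 of the same chromosome had 9 partners as well, but its group held only 12 loops and 2 closed triangles. On chromosome 15, the anchor at 102073660 to 102073882 had 10 partners, 5 on each side. On chromosome 5, the anchor at 118885698 to 118885913 had 9 partners, 3 upstream and 6 downstream. The anchor ending at 65253379 on chromosome 5 had 9 partners, all of them upstream. The anchor at 3212147 to 3212349 on chromosome 7 had 9 partners, 8 of them downstream, and 3 of its loops were longer than 5 Mb.

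**Figure D2:**
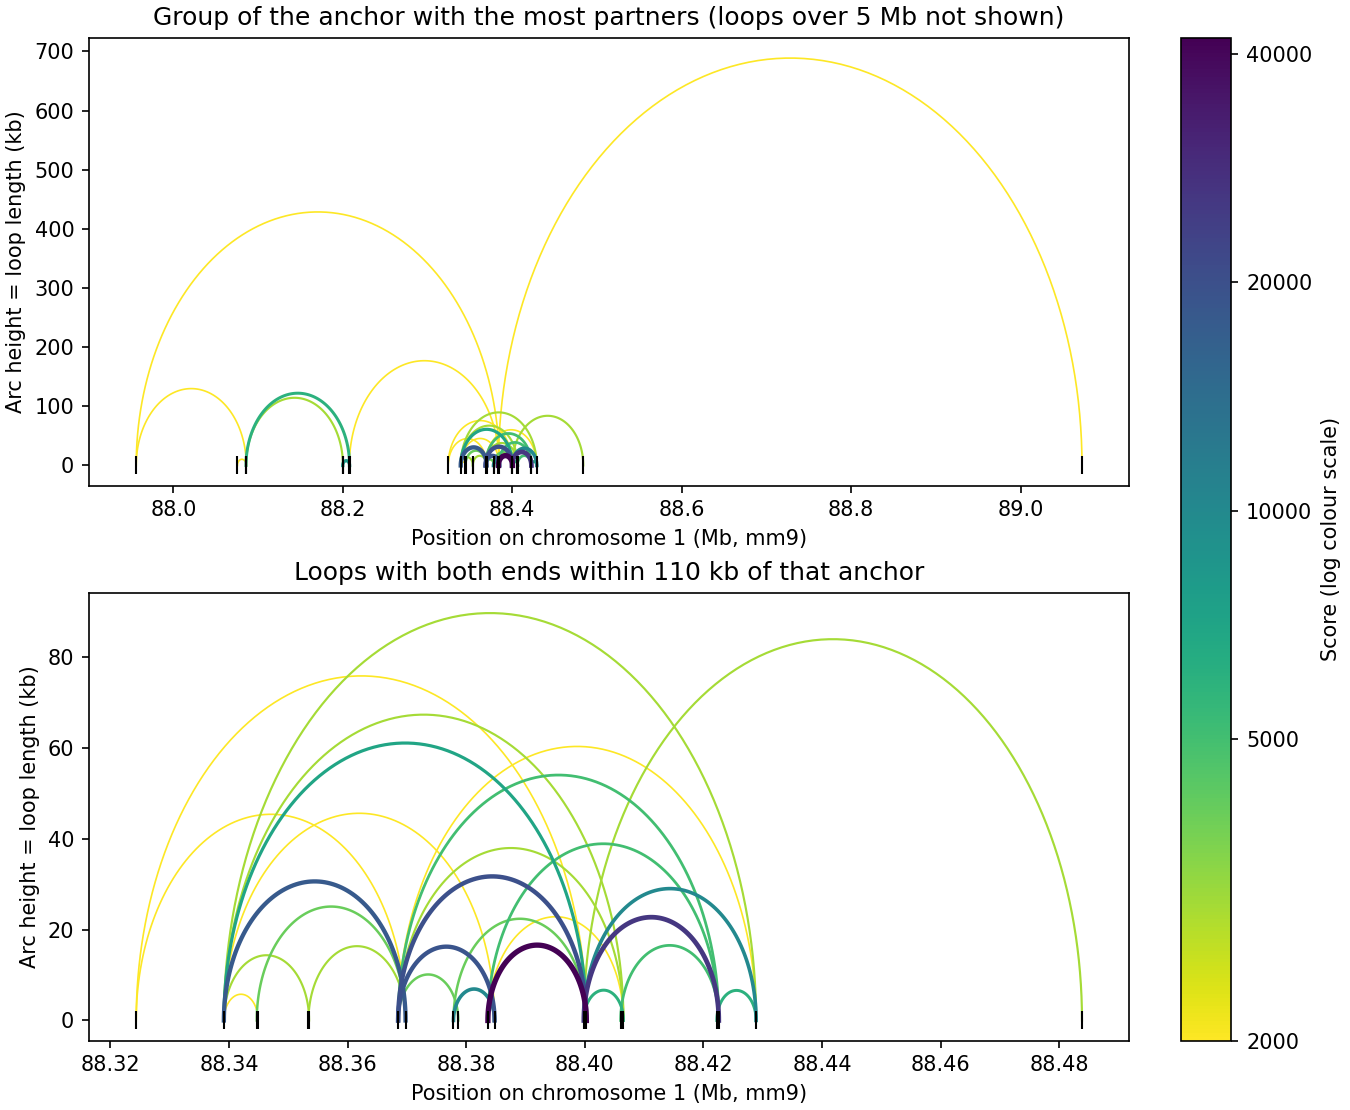
Loops of the group on chromosome 1 (mm9) that holds the anchor at 88383662, which had 11 partners over all loops and 9 without the 2 loops over 5 Mb, which are not drawn. The horizontal axis is position in Mb, each arc joins the outer edges of 1 loop with a height equal to its length in kb, colour and line width give the score, and ticks on the baseline are loop edges; the upper panel shows the 36 loops of the group and the lower the 28 with both ends within 110 kb of that anchor. The darkest arc is the loop with a score of 42000, and the longest arc, ending at 89072553, has the lowest score, 2000.

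Anchors fell into 2662 connected groups. Of these, 1477, or 55.5%, were a single loop between 2 anchors, while 137 groups of 10 or more anchors held 2360 loops, or 30.5% of the list. The largest group, on chromosome 17 from 34700960 to 84587929, had 44 anchors, but it was held together by loops over 5 Mb. Without those loops, the largest group lay on chromosome 15 from 99251015 to 102501664, with 33 anchors and 43 loops. The next lay on chromosome 17 from 83677087 to 84587929, with 25 anchors and 31 loops within 911 kb.

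The 5 longest loops each had the lowest score, 2000. They ran from 10001687 to 170000150, from 6243343 to 165813007 and from 29744584 to 181049004 on chromosome 2, from 3212147 to 152127675 on chromosome 7 and from 59029742 to 193666320 on chromosome 1. Their lengths were 135 to 160.0 Mb. Among the 162 loops over 5 Mb, 155, or 95.7%, had a score of 2000.

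Loops were unevenly spread over the chromosomes, most of all on chromosome X. Chromosome X held 65 loops where 345 were expected from its protein-coding genes, a ratio of 0.188 (interval with groups resampled 0.123 to 0.269). Chromosome 11 held 814 loops against 575 expected, a ratio of 1.42 (1.14 to 1.70), and chromosome 17 held 550 against 379, a ratio of 1.45 (1.003 to 1.96). By the exact binomial test over loops, the Benjamini-Hochberg adjusted p was 3.6e-77 for X, 1.1e-21 for chromosome 11 and 1.4e-16 for chromosome 17. This test called 9 of the 20 chromosomes, 4 above and 5 below expectation, and with autosomes alone it called 4 above and 8 below. For 6 of the 9 (chromosomes 7, 10, 13, 14, 15 and 16) the interval with groups resampled included a ratio of 1, so these calls did not hold by that interval with gene number as the expectation. By the extent between the outermost anchors, the intervals of chromosomes 13, 14 and 16 lay below 1 (0.477 to 0.883, 0.499 to 0.885 and 0.471 to 0.919). By extent, the interval of chromosome 3 also lay below 1 (0.505 to 0.955) and that of chromosome 19 above 1 (1.17 to 2.10). The test by gene number called neither of them. Chromosome 7 lay at 0.848 by gene number and at 0.765 with 1 loop per connected group (adjusted p = 0.00057, exact binomial test). By extent it lay at 1.34 instead (1.002 to 1.70 with groups resampled). By extent, the ratios were 2.24 on chromosome 11 (1.80 to 2.69 with groups resampled) and 2.08 on chromosome 17 (1.44 to 2.81). With 1 loop per connected group, chromosome 17 moved to a ratio of 0.936 and chromosome 11 to 1.17 (adjusted p = 0.089, exact binomial test), while X stayed below expectation at 0.362. This setting counts groups, and groups can merge where loops are dense, so it can lower the ratio of loop-rich chromosomes by construction. Per Mb of extent, chromosome 11 held 6.89 loops, chromosome 17 6.43 and chromosome 7 4.12, against 0.427 on X. Anchors of chromosome 17 had a mean of 2.01 partners, against 1.64 over the whole list and 1.27 on X. No loop was listed on chromosome Y. Median loop length ranged only from 23.0 kb on chromosome 19 to 31.6 kb on chromosome 18.

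**Figure D3:**
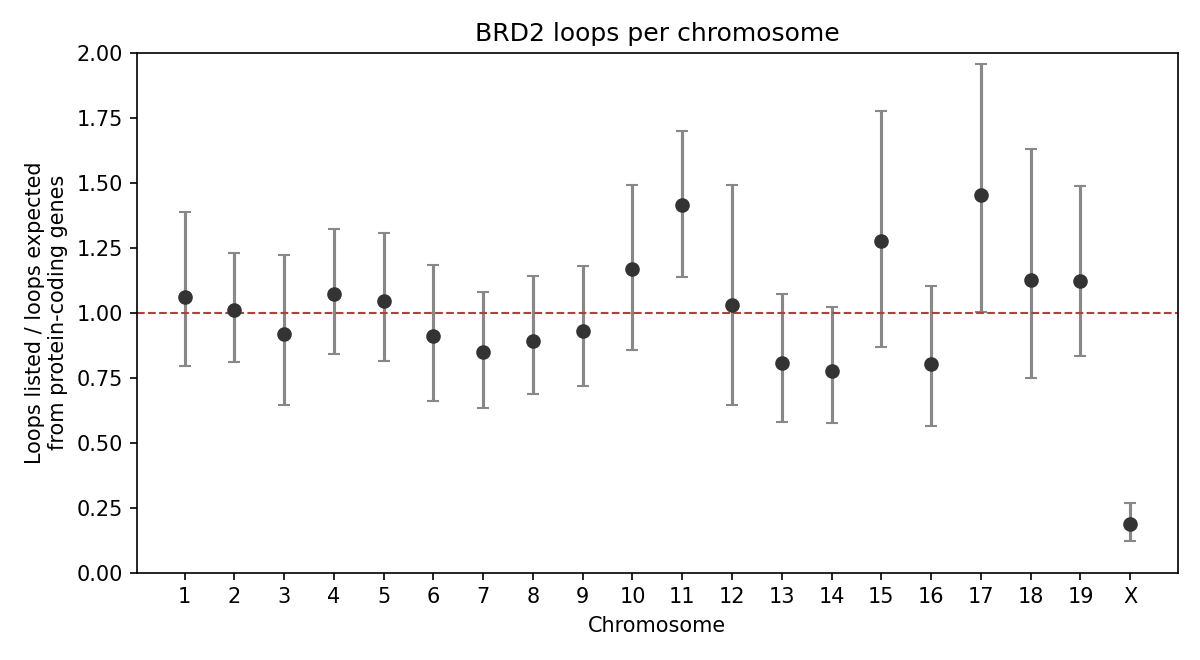
Ratio of listed loops to the number expected from protein-coding genes (vertical axis) for each chromosome (horizontal axis). Points are ratios, bars are 95% intervals from resampling whole connected groups, and the dashed line marks a ratio of 1; chromosome X lies at 0.188, and chromosomes 11 and 17 at 1.42 and 1.45.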

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

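With a minimum score of 3000, 3260 loops with a summed score of 14869000 remained, their median length was 19.2 kb, and 25.2% of anchors had 2 or more partners in 1749 connected groups. The median length was 39.1 kb over loops longer than 10 kb. Over the 1309 loops with both edges of both anchors known, it was 27.9 kb between outer edges, inside the interval of the whole list, and 27.5 kb between midpoints and 27.0 kb between inner edges, just below it. Joining all edges closer than 10000 bp lowered the share of anchors with 2 or more partners to 34.9%. Pairing edges within 2000 bp gave the same anchors, since none was wider than that, so this setting tested nothing. The negative relation of score and length kept its sign and stayed past the threshold under the 4 alternatives run on the whole list, with rho from -0.27 to -0.25. Within single chromosomes the coefficient was below 0 on 20 of 20, from -0.32 to -0.14, and passed the adjusted threshold on 19, the exception being chromosome X with 65 loops (adjusted permutation p = 0.268). The number of chromosomes past the threshold was 16 (6 above, 10 below) with the extent between the outermost anchors as expectation, 12 (6 above, 6 below) without olfactory, vomeronasal and trace amine receptor genes, and 2 (X and 7, both below) with 1 loop per connected group, where 2662 loops remain. With the extent, chromosome 7 reversed to a ratio of 1.34, and without the receptor genes its ratio was 0.994. Without those genes, chromosomes 2 and 19 (above) and 3 and 8 (below) passed the threshold. With 1 loop per group, chromosome 16 reversed to 1.07 and chromosome 17 to 0.936, neither past the threshold. The cause was not tested. Chromosome X stayed below expectation in the 5 alternatives that include it, with ratios from 0.139 to 0.362. The summed score and the number of connected groups at a minimum score of 3000, the extent, the receptor genes, autosomes alone, the 1 Mb and 5 Mb limits, single chromosomes, the use of midpoints and outer edges over only those 1309 loops and the 10000 bp rule were chosen after seeing the data. Not run were a stricter q-value and a larger overlap of anchors, for which the list has no values, every alternative that needs genes at anchors, and leaving out a replicate, since the list is merged. No paired analysis was possible because the study has 1 group. The unknown depth limits what a missing loop means, since 57.8% of the loops sit at the lowest score.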

Other observations

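Some anchors had listed partners in only 1 direction. Counting loops of up to 1 Mb, 603 anchors had 4 or more partners, and 110 of them, or 18.2%, had all partners on 1 side, 56 downstream and 54 upstream. These 110 had a median of 14 listed anchors within 1 Mb on the used side and 7 on the unused side, where 16 had no listed anchor at all. The count on the used side includes the 4 or more partners themselves, so part of this difference follows from how these anchors were chosen. The anchor ending at 65253379 on chromosome 5 had 9 partners upstream and none downstream. The anchor starting at 12795225 on chromosome 12 had 8 partners downstream, and the one starting at 88339145 on chromosome 1 had 7 downstream. The anchor ending at 37334120 on chromosome 17 had 7 partners, all upstream, and was the downstream end of its group.

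The tests of the next 3 patterns were set before the values of the tests were seen, except both tests on chromosome X. One-sided anchors as a pattern, and the limits of 1 Mb and 5 Mb used in these tests, were chosen after the data were seen. One-sided anchors were more frequent than in draws made from the placing of anchors. When partners were drawn by distance from the listed anchors within 1 Mb, 1000 draws gave a median of 80 one-sided anchors and a middle 95% of 68 to 92.0, against 110 observed. When anchors with more partners were also made more likely to be chosen, the draws gave 93 (80 to 105). The range by distance is not exact. Of 40 simulated lists laid by distance alone, 15 lay inside their draws, 25 below and 0 above. The draws by anchor strength were not tested in this way. In both sets of draws, partners were drawn for each anchor separately, whereas listed anchors share loops and lie in groups. Both ranges may therefore be too narrow, which the simulated lists do not settle, since their loops were placed independently. Anchor spacing and uneven anchor strength gave fewer one-sided anchors than observed as modelled. A domain border beside such anchors is a candidate explanation that stays untested, since no other mark of borders was used here. Loops that pass over one-sided anchors were not counted either. Among the named ones, that at 88339145 on chromosome 1 was passed over by the loop from 88324363 to 88400259, among others. Those ending at 65253379 on chromosome 5 and 37334120 on chromosome 17 were the downstream ends of their groups.

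Whether loops longer than 5 Mb are chance ligations between strong anchors could be examined for only 53 of the 162. The 53 such loops with a local loop at both ends had a median length of 31.5 Mb between anchor midpoints. In 1000 draws of anchor pairs weighted by local summed score, the median was 39.991 Mb and the range 27.2 to 53.5 Mb. The observed length lay inside this range, on the short side of the draw median. With so wide a range, the test did not reject chance ligation, but it does not show it either. Pairs of distant loops with both ends within 100 kb of each other, as neighbouring anchors that support a contact would give, numbered 0, where draws gave 0 to 2. Chance alone also gave a median of 0, so the outcome set beforehand as evidence against such support decides nothing. Anchors that carry both a distant and a local loop had a median local summed score of 5000, against 3000 for other anchors with a local loop. Only 55.6% of the 313 anchors of distant loops had a local loop, however. The rest had none and are left out of this contrast, so it does not show that distant loops in general join strong anchors. The other 109 distant loops could not be set against these draws, and no biological explanation was tested.

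The low number of loops on chromosome X stays partly open. V6.5 is a male line with a single X, which lowers the number of tags per place. If 1000 of score is 1 tag, halving the tags would keep 42.4% of autosomal loops, and the X ratio corrected for this was 0.444 (0.290 to 0.634). This value was still below that of the lowest autosome, chromosome 14, at 0.776. The interval of chromosome 14 with groups resampled was 0.577 to 1.02, however, and overlaps that of the corrected X ratio. A wholly copy-number effect still cannot be told apart from others, because the unit of the score and the other filters of the caller are not given: if only 25% of loops were kept, the upper end of the interval would be 1.08. Whether gene number overstates the expectation also stays open. The ratio by extent was 0.139 (0.0903 to 0.198) against 0.664 on the lowest autosome, but extent sets a higher expectation for X than gene number does, so this test could not have favoured that explanation. The share of X loops at the lowest score was 58.5% (45.6 to 70.6%), which includes both the autosomal 57.8% and the 66.0% predicted by halving.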
